A study of Homo sapiens with 9 samples.

How the data were processed

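RNA was measured in 9 libraries of CI-huVEC, a commercial immortalized line of human umbilical vein endothelial cells, at passage 31 per the labels. The 3 groups of 3 libraries were wild-type lines 1, 2 and 3, knockout clones 21, 22 and 23, and the same knockout clones grown on fibronectin at 5 µg per square centimetre for 48 h. The knockout clones carried CRISPR/Cas9 edits in exon 3 of CCM3, which the files list as PDCD10. Every library was placed in its group by its label, and 0 columns were left without a sample.

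The authors made stranded poly-A libraries with a TruSeq kit per the labels, and deposited a table of raw counts per gene symbol for the 9 libraries. Per the submitters' processing notes the tools included STAR, an aligner, and HTSeq, a read counter, with the hg19 (GRCh37) build, and their versions and the strand setting of the counting were not given in the sources used here. The authors also deposited FPKM values per gene and library, which normalise counts for depth and gene length. In every library those FPKM values were proportional to the counts divided by a length per gene, with a largest deviation of 0.0158% to 0.0188% at the 99th percentile over 7669 genes, so the FPKM values were used only for this check. The authors further deposited tables of their own comparisons with a log2 fold change, a p-value and an adjusted p-value per gene, and the program behind them was not given in the sources used here. Between 12 and 13 gene names in each of those tables had been turned into dates and were left out of the overlaps.

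The count table held 28514 gene symbols, of which 7794 had a count of 0 in all 9 libraries. Total counts per library ran from 24406001 to 33971610, and 16703 to 17228 genes had at least 1 count. Within each group the counts of replicate pairs differed by more than sampling noise, with a chi-square per degree of freedom of 5.37 to 21.8 over genes with at least 20 counts in the pair, so no library looked like a repeat of another. Symbols were used as the file gives them, some of which are older names. The reference available was GRCh38, so none of its coordinates were used, and it served only for GC content and for which chromosome a gene lies on.

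Differential expression was tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test with robust dispersion, TMM scaling and 1 fit over all 9 libraries. Genes were kept by filterByExpr with its default minimum count of 10 and total of 15, which left 13802 genes. Adjusted p-values are Benjamini-Hochberg values over all tested genes, and a gene counts as risen or fallen at an adjusted p under 0.05. Levels are CPM, counts scaled to a common TMM-corrected library size, computed from the deposited counts, as mean ± SD over the 3 libraries of a group. Standard errors of log2 fold changes come from the edgeR fit. A group with 0 counts in all of its libraries was set to a floor of 3 counts over the group, which gives a lower bound, and with 1 to 3 counts a ratio is given with its 95% exact counting interval. These bounds and intervals cover counting error only.

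The 32 gene lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 29 lists that had at least 5 tested members. Camera with an estimated correlation and fry, a directional set test, were run beside it. Named genes followed a rule. It took PDCD10 and, for each comparison with wild-type, the 10 highest and 10 lowest log2 fold changes among changed genes with a mean of at least 5 CPM and groups that did not overlap. It also took the 10 smallest p-values on fibronectin, the 10 highest and lowest changes with the clone as a block, up to 4 members of each list with the smallest p-values, and 13 genes named in advance. Genes without a standard symbol were left unnamed, a limit written for the comparisons with wild-type and applied to the others too. The grouping, tests, gene lists, naming rule and first set of alternatives were fixed before the data were examined.

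The knockout and knockout-on-fibronectin groups hold the same 3 clones per the labels, so their libraries are paired. Deviations from the group means correlated across 9384 genes at r = 0.30, 0.43 and 0.50 within the same clone, against -0.47 to 0.07 between different clones. Deviations cancel out over the libraries of a group, so positive values within clones by themselves lower those between different clones. The fit with the clone as a block used the 6 libraries of those groups and 13257 genes.

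Because both comparisons with wild-type share their controls, 20 simulations of unchanged groups against the same wild-type means and spread gave the correlation and covariance that shared controls alone produce, without modelling the clones that the groups also share. The share of the knockout effect reversed by fibronectin was measured in each clone on genes called in the other 2 clones, as minus the slope of the difference on fibronectin on the knockout log2 fold change, so that genes were not chosen on the libraries measured.

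The gene tests, the blocked fit with its GC correction, the list tests for knockout against wild-type and the share reversed were tested on simulated counts with known changes, and the other steps were not. For the knockout against wild-type (13501 genes) the test found 28%, 74%, 96% and 98.0% of genes changed 1.25, 1.5, 2 and 4-fold, and called 9 of 13302 unchanged genes. For the knockout on fibronectin against wild-type (13486 genes) the shares were 32%, 74%, 90% and 100%, with 13 of 13286 unchanged genes called. For fibronectin against none (13504 genes) they were 4%, 56%, 90% and 98.0%, with 0 of 13305 called, and with the clone as a block (13397 genes) 14%, 64%, 94% and 100%, with 10 of 13198 called. An added GC trend raised the last number to 162 of 13198, and the GC correction brought it to 15 of 12283. A list raised on purpose was called by camera in both forms and by fry. Genes were simulated independently of each other, so this does not test the choice of the preset correlation. A simulated reversal of 0 was recovered as -0.00497 and one of 0.5 as 0.425, so the measure understates a partial reversal. The simulated knockout log2 fold changes were limited to 4 in size, while called ones in the data reached 13.2. The understatement in the data may therefore differ from the simulated one.

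The alternatives were DESeq2 1.42.0 and limma-voom as tools, other scaling factors, no low-count filter and a filter of at least 1 CPM in 3 libraries, fits of only the 2 groups compared, the clone as a block or a random effect, a 2-fold minimum, other list tests and leaving out each library in turn. A correction of each library for a smooth trend on gene GC content (lowess span 0.3) was added after seeing the data, as were the further settings of the blocked fit. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Left out were the 3 lists with too few tested members, for which only member counts are given, sex-linked marker genes, a few genes that the naming rule took and that are not reported here, and read-level questions such as the edit itself, which gene counts cannot show.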

Results

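The data are gene counts of poly-A RNA from 9 libraries of CI-huVEC, an immortalized human umbilical vein endothelial cell line. CCM3, listed as PDCD10, is one of the genes mutated in familial cerebral cavernous malformations, and its product joins kinases of the GCKIII family to the STRIPAK complex. The groups were 3 wild-type lines, 3 clonal knockout lines (clones 21, 22 and 23) and the same 3 clones after 48 h on fibronectin, an extracellular matrix protein. Total counts were 26453753, 29270579 and 30280241 in wild-type, 25982627, 27468896 and 29930894 in knockout, and 28743719, 24406001 and 33971610 in knockout on fibronectin. The labels call the wild-type samples lines but do not say whether they came from separate cultures, so p-values may measure only the spread between these samples. The knockout lines are clonal per the labels and the same is not said of the wild-type lines, so clonal origin and genotype are not separated in any comparison with wild-type. In a principal component analysis PC1 carried 83.7% of the variance and parted the 3 wild-type libraries from the other 6, and PC2 carried 7.37%.

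PDCD10 itself, the edited gene, had a lower CPM in every knockout library than in every wild-type library, but its mRNA was not lost. Its counts were 1252, 1439 and 1617 in wild-type, 1105, 978 and 1120 in the knockout clones and 1052, 852 and 1220 in the same clones on fibronectin. That is 49.3 ± 3.49 CPM in wild-type, 38.5 ± 3.43 in knockout and 36.4 ± 1.30 on fibronectin (SD, n = 3 each). The knockout fell by 0.36 on the log2 scale (SE 0.08, adjusted p = 0.00186) and the knockout on fibronectin by 0.44 (adjusted p = 0.000326). An edit that shifts the reading frame need not remove the transcript, so gene counts do not show the edit itself.

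The first comparison, knockout against wild-type, asks how the CCM3 knockout changed the endothelial transcriptome. The largest loss by abundance was in FN1, the fibronectin gene, which went from 14675 ± 764 CPM to 1406 ± 28.4 CPM (SD, n = 3 each), 10.4-fold lower (log2 fold change -3.38, SE 0.09, adjusted p = 4.02e-12). FN1 took 1.42% to 1.59% of all counts in wild-type libraries and 0.137% to 0.144% in knockout libraries. The flow-responsive transcription factors KLF2 and KLF4 rose 9.46-fold and 8.28-fold, from 7.0 ± 0.925 to 66.4 ± 5.16 CPM and from 3.33 ± 0.405 to 27.5 ± 1.60 CPM (SD, n = 3 each). Of 25 TGF-beta and BMP response genes 19 fell and 3 rose (camera adjusted p = 5.57e-07, and adjusted p = 0.0682 with an estimated correlation). Among those that fell were TGFBI, a secreted matrix protein, from 476 ± 10.6 to 46.8 ± 3.21 CPM and ID3, a BMP target, from 97.2 ± 2.73 to 8.32 ± 0.824 CPM (SD, n = 3 each).

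Gene groups that rose were led by the list of the KLF2 and KLF4 axis, which holds both factors themselves. In the KLF2 and KLF4 axis 15 of 16 tested members rose and 1 fell, with the same counts adjusted over the list alone. Its members included THBD, which encodes the anticoagulant receptor thrombomodulin (log2 fold change 1.95, SE 0.08), ADAMTS4, a proteoglycan-cleaving protease (2.83, SE 0.09) and PPAP2B, a lipid phosphatase (1.64, SE 0.07). The list's camera adjusted p = 5.24e-09, and it was the only list still called with an estimated correlation, with adjusted p = 0.0139 with an estimated correlation. Of 39 endothelial identity genes 25 rose, 5 fell and 9 were not called (camera adjusted p = 3.19e-05, and adjusted p = 0.195 with an estimated correlation). SELP, the leukocyte adhesion molecule P-selectin, rose 47.6-fold from 1.49 to 71.2 CPM, the angiopoietin receptor gene TEK rose 3.62-fold and PECAM1, an endothelial junction protein, rose 2.31-fold, whereas CDH5, the VE-cadherin gene, had a log2 fold change of -0.06 (adjusted p = 0.523). Of 25 cholesterol synthesis genes 17 rose, 1 fell and 7 were not called, with FDFT1, squalene synthase, at 0.80 on the log2 scale (camera adjusted p = 1.97e-06, and adjusted p = 0.219 with an estimated correlation).

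Among 34 interferon response genes 18 rose, 7 fell and 9 were not called, or 19 and 8 adjusted over the list alone (camera adjusted p = 0.0317, and adjusted p = 0.61 with an estimated correlation). Its camera adjusted p was 0.0827 without wild-type library 3, 0.0643 without knockout clone 21, and 0.0529 and 0.0598 without clones 21 and 23 on fibronectin. PSMB9 and TAP1, which serve antigen processing, rose by log2 fold changes of 3.87 and 1.12, whereas BST2, an antiviral membrane protein, fell by 3.24 on the log2 scale. Of 48 cytosolic ribosomal protein genes 22 rose and 26 were not called, with a list median log2 fold change of 0.16 (camera adjusted p = 0.000654, and adjusted p = 0.671 with an estimated correlation). Of 7 tested replication-dependent histone genes 5 rose and 2 were not called (camera adjusted p = 0.0173, and adjusted p = 0.229 with an estimated correlation). Ribosomal protein genes have many processed pseudogenes, histone genes have near-identical copies and most histone mRNA lacks a poly-A tail, so the values of both families are uncertain. For the lists of this comparison, counts adjusted over the list alone were the same where none are given.

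The groups that fell were led by TGF-beta signalling. Of 25 TGF-beta and BMP response genes 19 fell, 3 rose and 3 were not called, or 20 and 3 adjusted over the list alone (camera adjusted p = 5.57e-07, and adjusted p = 0.0682 with an estimated correlation). ATOH8, a transcription factor downstream of BMP receptors, fell by 5.56 on the log2 scale (SE 0.14) and PMEPA1, a feedback inhibitor of TGF-beta signalling, fell by 2.23 (SE 0.09). Among 17 mesenchymal genes 12 fell, 3 rose and 2 were not called (camera adjusted p = 0.0173, and adjusted p = 0.195 with an estimated correlation). SNAI1, a repressor of epithelial and endothelial genes, and SPARC, a matrix protein, fell by 1.91 and 0.76 on the log2 scale, and CDH2, N-cadherin, by 0.66, while LOX, which crosslinks collagen, rose by a log2 fold change of 1.56. Of 41 extracellular matrix genes 22 fell, 10 rose and 9 were not called (camera adjusted p = 0.0134, and adjusted p = 0.61 with an estimated correlation). Of 33 actin contractility genes 19 fell, 8 rose and 6 were not called, or 20 and 8 adjusted over the list alone (camera adjusted p = 0.0372, and adjusted p = 0.229 with an estimated correlation). TAGLN and TPM1, which bind actin filaments, fell from 44.7 to 11.2 CPM and from 258 to 112 CPM.

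Other lists were not called by camera, which compares a list with all other genes, although fry, which does not, called 21 of the 29 lists. Among those called by fry alone were the Notch pathway (adjusted p = 0.00014), angiogenic genes (0.000114), YAP and TAZ targets (0.000982) and inflammatory genes (0.00172), all downward, and the CCM complex upward (0.0035). In the CCM complex and its partners 7 of 22 genes rose, 5 fell and 10 were not called (camera adjusted p = 0.152, with a positive median and a negative mean). CCM2L, a paralog of CCM2, rose 10.8-fold and HEG1, a receptor that binds KRIT1, rose 2.87-fold, whereas MST4, a GCKIII kinase that binds CCM3, fell from 16.3 ± 2.55 to 0.0735 ± 0.0961 CPM (SD, n = 3 each). Its counts in the knockout clones were 1, 5 and 0, so the size of its fall is uncertain, with a log2 fold change of -7.73, and of -9.51 and -7.12 without knockout clones 22 and 23. The other familial CCM genes KRIT1 and CCM2 had log2 fold changes of 0.15 (adjusted p = 0.0701) and 0.19 (adjusted p = 0.108). In the Notch pathway 5 of 19 genes rose, 11 fell and 3 were not called (camera adjusted p = 0.149). Its transcription factor gene HEY2 held 1 count over the 3 knockout libraries, a ratio of 1127 (interval 202 to 44524), and the ligand genes JAG1 and DLL1 had log2 fold changes of -0.73 and 1.87. Of 36 integrin and focal adhesion genes 8 rose, 18 fell and 10 were not called, or 9 and 18 adjusted over the list alone (camera adjusted p = 0.2). Fry called that list downward (adjusted p = 0.0466). The integrin subunit genes named in advance, ITGAV, ITGB3, ITGA5 and ITGB1, had log2 fold changes of -1.72, -1.24, -0.77 and -0.47, and ITGA6, a laminin receptor subunit, rose by a log2 fold change of 1.85. Of 32 matrix proteases and inhibitors 10 rose, 12 fell and 10 were not called, or 10 and 13 adjusted over the list alone (camera adjusted p = 0.997). The stromelysin gene MMP10 fell 15.4-fold.

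Of 25 YAP and TAZ targets 6 rose, 12 fell and 7 were not called, or 6 and 13 adjusted over the list alone (camera adjusted p = 0.144), and CTGF and ANKRD1, commonly used readouts of that pathway, fell by 1.11 and 1.06 on the log2 scale. Of 44 angiogenic and tip cell genes 13 rose, 21 fell and 10 were not called, or 13 and 22 adjusted over the list alone (camera adjusted p = 0.152). ANGPT2, an antagonist of the TEK receptor, fell 4.81-fold, and the chemokine receptor gene CXCR4 and the G protein regulator RGS5 had log2 fold changes of -4.13 and -3.97. Of 33 cell junction genes 13 rose and 13 fell, or 14 and 14 adjusted over the list alone, and 7 were not called (camera adjusted p = 0.868, upward, with a median of -0.06). Of 27 inflammatory and NF-kB genes 6 rose, 13 fell and 8 were not called (camera adjusted p = 0.119), with log2 fold changes of -3.79 for PTGS2, the inducible cyclooxygenase, and -3.31 for the chemokine gene IL8. Of 23 coagulation genes 10 rose, 8 fell and 5 were not called (camera adjusted p = 0.545, upward, with a negative median and mean). Of 36 proliferation genes 5 rose, 16 fell and 15 were not called, or 5 and 17 adjusted over the list alone (camera adjusted p = 0.152), with CDK1 at -0.42 and TOP2A at -0.44 on the log2 scale.

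The lymphatic markers moved apart, as LYVE1, a hyaluronan receptor, rose 11.6-fold from 26.0 to 302 CPM and PROX1, the transcription factor of lymphatic fate, fell by 3.80 on the log2 scale (-4.45 without knockout clone 23), with 2 of 7 tested members up, 3 down and 2 not called, or 2 and 4 adjusted over the list alone (camera adjusted p = 0.569). Lists of stress and survival genes also held members that rose and members that fell. Fry called the p53 targets (adjusted p = 0.0308), apoptosis regulators (0.0128), hypoxia and glycolysis (0.0468) and the oxidative stress response (0.00693) upward. It did not call the unfolded protein response or the autophagy genes. For p53 targets 9 of 23 rose, 4 fell and 10 were not called (camera adjusted p = 0.204, with a positive median and a negative mean). For apoptosis regulators 12 of 33 rose, 8 fell and 13 were not called (camera adjusted p = 0.412), and CASP1, an inflammatory caspase, rose by a log2 fold change of 2.50. For hypoxia and glycolysis 11 of 33 rose, 9 fell and 13 were not called (camera adjusted p = 0.667). For the unfolded protein and amino acid stress response 8 of 22 rose, 5 fell and 9 were not called (camera adjusted p = 0.783, with a positive median and a negative mean). For autophagy and lysosome genes 6 of 23 rose, 5 fell and 12 were not called (camera adjusted p = 0.764, with a positive median and a negative mean). For the oxidative stress response 11 of 24 rose, 7 fell and 6 were not called, or 11 and 8 adjusted over the list alone (camera adjusted p = 0.119).

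Markers of other cell types were few among the tested genes. Of 5 tested smooth muscle and pericyte markers 3 fell and 2 were not called (camera adjusted p = 0.093, and fry adjusted p = 4.33e-06, downward). Camera called that list downward, with adjusted p from 0.0286 to 0.0475, when any library other than wild-type 1 or 2 was left out. The members that fell include RGS5, SMTN and TAGLN. Of 5 tested fibroblast markers 1 rose, 2 fell and 2 were not called (camera adjusted p = 0.783, and fry adjusted p = 0.0148, downward). The epithelial and leukocyte lists had 4 tested members each, too few for the set test. KRT18, KRT8 and EPCAM rose and KRT7 fell by 1.49 on the log2 scale, and LYZ, CD14, CD68 and ITGAM rose, of which LYZ, CD14 and ITGAM had means under 1 CPM in knockout. EPCAM lay low as well, at 0.583 to 1.11 CPM in the knockout libraries. It was not called without wild-type library 1 (adjusted p = 0.0838) or knockout clones 21 (0.0826) and 23 (0.0522). None of 13 mitochondrially encoded gene names matched the file. 

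The changes of greatest size were differences between an expressed and a nearly silent state. POSTN, a matrix protein of connective tissue, had 42.6 ± 2.48 CPM in wild-type (SD, n = 3) and 0 counts in the knockout libraries, at least 1184-fold lower, and AMTN, an adhesion protein of tooth enamel, was at least 458-fold lower. FBLN5, an elastic fibre protein, and PTK7, a WNT-pathway receptor, had log2 fold changes of -9.71 and -7.84. SLITRK4 and MAL2 had ratios of 1255 (interval 347 to 10360) and 503 (interval 172 to 2440), and PCSK6 and SULT1E1 were 210-fold and 181-fold lower. In the other direction FAM65B, a RhoA-binding protein, was at least 433-fold higher, and PGM5 and CMKLR1, a chemerin receptor, had ratios of 1230 (interval 340 to 10156) and 964 (interval 267 to 7962). Higher too were SCUBE1 and CLIC2, with log2 fold changes of 9.19 (9.92 without wild-type library 1) and 9.07, CPE, a prohormone-processing enzyme (8.51), PPP2R2C (7.89), DNASE1L3, a secreted nuclease (7.59, or 6.97 without knockout clone 21) and ST6GALNAC1 (7.53), and KIF19 had a ratio of 232 (interval 79.2 to 1123).

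Over all genes, 6913 of 13802 (50.1%) changed in the knockout, 3180 up and 3733 down by edgeR, and 1827 of them changed at least 2-fold, 793 up and 1034 down. The groups did not overlap for 8483 genes, where chance gives 10% of the genes. Medians of whole chromosomes also differed between knockout and wild-type, from -0.17 to 0.09 on the log2 scale.

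**Figure D1:**
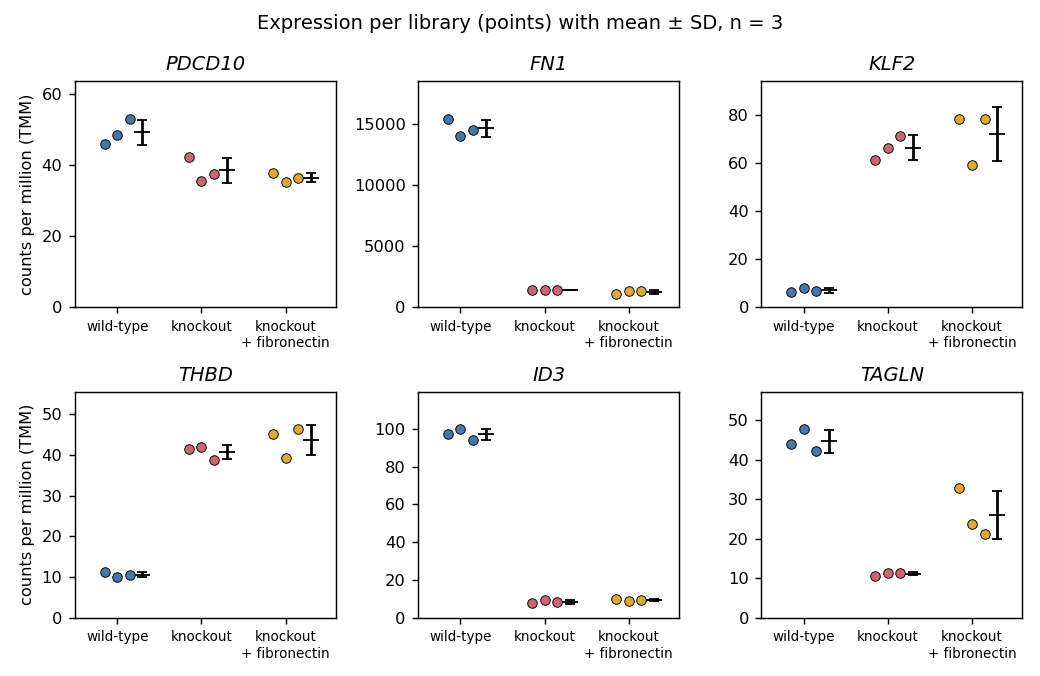
Level in CPM (vertical axes, linear, from 0) of single genes in each library of wild-type, knockout and knockout on fibronectin, with points for libraries and bars for the mean and SD of 3 libraries. FN1 lies near 14675 CPM in wild-type and near 1406 CPM in knockout, and TAGLN goes from 11.2 CPM in knockout to 25.9 CPM on fibronectin.

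**Figure D2:**
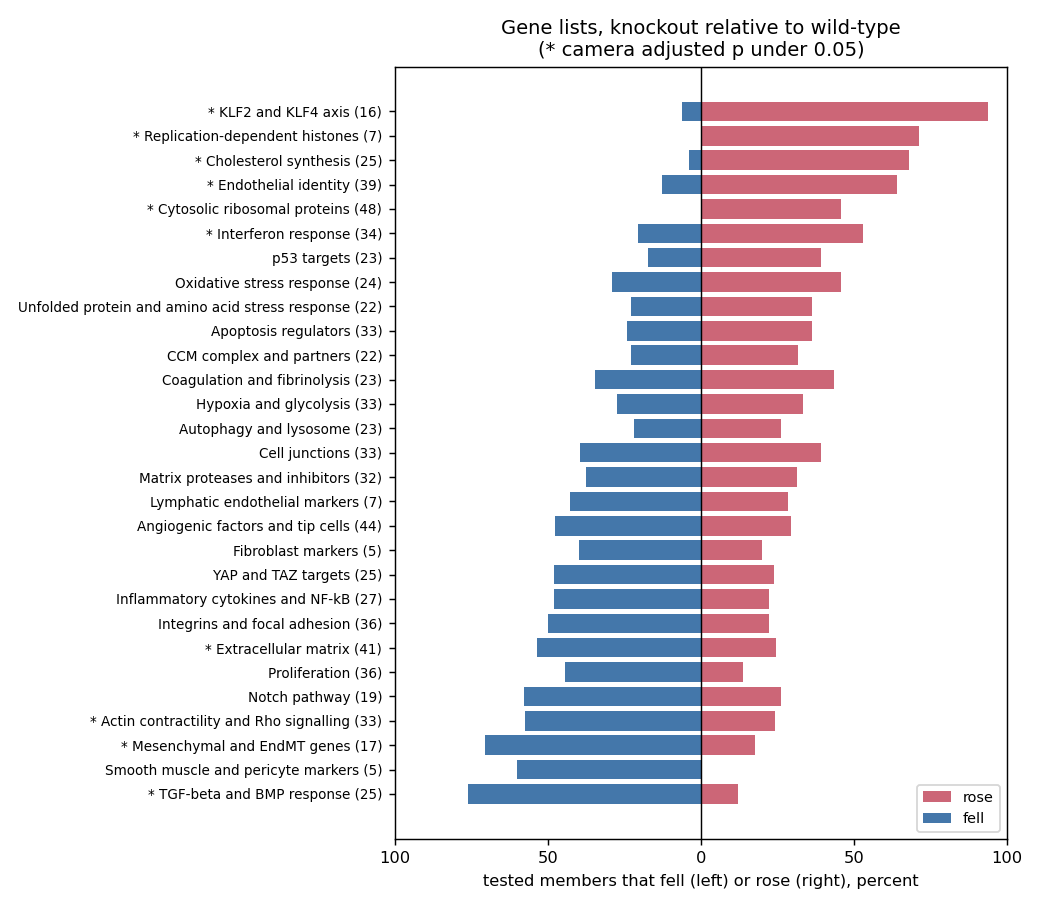
Percent of the tested members of each gene list with at least 5 of them that rose (right) or fell (left) in the knockout against wild-type, with the number tested in parentheses and an asterisk for a camera adjusted p under 0.05. The KLF2 and KLF4 axis has 15 of 16 members up, and the TGF-beta and BMP response has 19 of 25 down.

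The second comparison, knockout on fibronectin against wild-type, asks what set the treated knockout cells apart from wild-type cells. FN1 stayed low at 1229 ± 142 CPM (SD, n = 3), with a log2 fold change of -3.58 against wild-type, and KLF2 and KLF4 stayed high at 72.1 ± 11 and 29.1 ± 1.60 CPM (SD, n = 3 each). SELP (log2 fold change 5.61), PECAM1 (1.21), TGFBI (-3.49), ID3 (-3.40) and ITGB1 (-0.72) all differed from wild-type in the direction seen without fibronectin. The most lowered genes included CST1, a cystatin protease inhibitor, from 361 to 1.56 CPM (log2 fold change -7.85, or -8.63 without treated clone 21). POSTN had 1 count over the 3 treated libraries, a ratio of 3654 (interval 656 to 144335), AMTN was at least 471-fold and HEY2 at least 387-fold lower, and FAM65B was at least 526-fold higher.

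The list test called 10 lists, and each of them except the oxidative stress response had been called in the first comparison. The KLF2 and KLF4 axis had 15 of 16 members up and 1 down (camera adjusted p = 1.61e-07), and adjusted p = 0.025 with an estimated correlation. Up as well were cholesterol synthesis with 22 up and 1 down (camera adjusted p = 6.37e-07), and adjusted p = 0.243 with an estimated correlation, ribosomal proteins with 42 up and 0 down, or 44 and 0 adjusted over the list alone (9.17e-08), and adjusted p = 0.554 with an estimated correlation, and endothelial identity with 23 up and 7 down (0.000474), and adjusted p = 0.269 with an estimated correlation. The interferon response with 21 up and 8 down, or 22 and 8 adjusted over the list alone (0.028), and the oxidative stress response with 13 up and 5 down (0.0479) each had adjusted p = 0.554 with an estimated correlation, and histones with 5 up and 0 down (0.0316) had adjusted p = 0.353 with an estimated correlation. The interferon call was lost without wild-type library 3 (adjusted p = 0.0605) or treated clone 21 (0.0566), and the histone call without treated clone 23 (0.0517). The oxidative stress call was lost without wild-type libraries 1 (0.0535) and 2 (0.0503), knockout clone 21 (0.0515) or treated clones 21 (0.0566) and 23 (0.0978). Down were the TGF-beta and BMP response with 3 up and 20 down, or 3 and 21 adjusted over the list alone (5.8e-07), and adjusted p = 0.0717 with an estimated correlation, mesenchymal genes with 3 up and 12 down, or 4 and 12 adjusted over the list alone (0.028), and adjusted p = 0.243 with an estimated correlation, and extracellular matrix with 11 up and 23 down (0.0153), and adjusted p = 0.554 with an estimated correlation. Actin contractility, with 8 up and 18 down, or 10 and 18 adjusted over the list alone, was not called (camera adjusted p = 0.132), and whether the list differed between the comparisons was tested only by setting the treated against the untreated clones.

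By edgeR 8099 of 13802 genes (58.7%) differed from wild-type, 4009 up and 4090 down, and 2010 by at least 2-fold, 913 up and 1097 down. The libraries' own correlations with gene GC content were -0.106, -0.0858 and -0.371 in wild-type and 0.431, 0.434 and 0.436 on fibronectin. With a GC correction, added after seeing the data, 7841 genes were called, 3842 up and 3999 down. The first comparison then had 7155, 3495 up and 3660 down. The counts of list members above are without that correction. The groups did not overlap for 8868 genes, where chance gives 10% of the genes. The changes of the comparisons with wild-type were shared in 2862 genes that rose and 3220 that fell, against 924 and 1106 for independent lists, and 0 genes were called in opposite directions among 13802. Across genes, which are not independent replicates, the log2 fold changes correlated at Pearson r = 0.973 and Spearman rho = 0.906, and unchanged groups simulated against the same controls gave r = 0.498 (range 0.466 to 0.530 over 20 simulations). The covariance was 1.34 against 0.0163 simulated, a difference of 1.33. The 3 wild-type libraries could not be split into parts of at least 2, so part of the excess in overlap and correlation may come from the shared controls. The compared groups also hold the same 3 clones, which the simulation does not model.

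**Figure D3:**
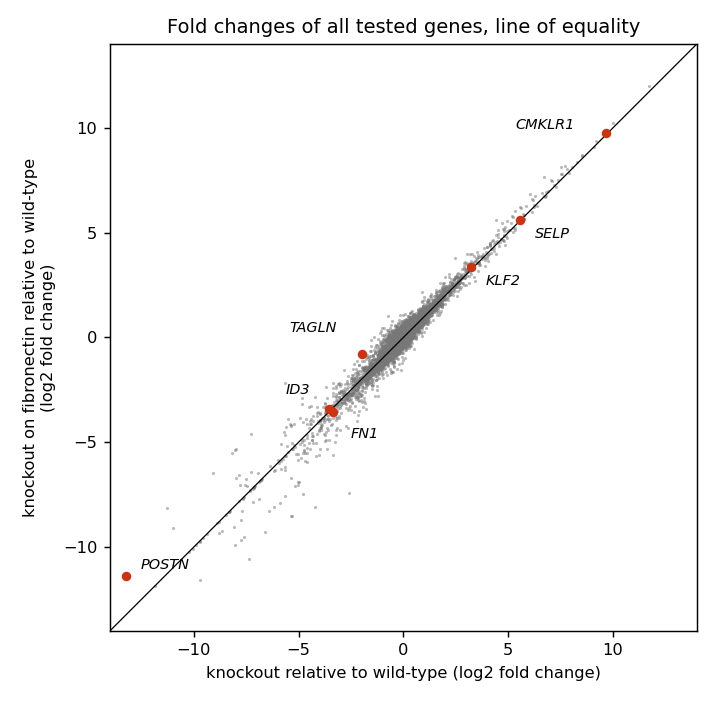
Log2 fold change against wild-type of each tested gene in the knockout (horizontal axis) and in the knockout on fibronectin (vertical axis), with the line of equality. Points follow the line with r = 0.973, and TAGLN lies above it; the position of genes with 0 counts in a group depends on the prior count of the fit.

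The third comparison, knockout on fibronectin against knockout, asks whether 48 h on fibronectin changed mRNA levels in the CCM3 knockout clones. TAGLN, which encodes transgelin, an actin-binding protein of contractile cells, rose 2.32-fold from 11.2 ± 0.408 to 25.9 ± 6.10 CPM (SD, n = 3 each), against 44.7 ± 2.73 in wild-type. It was the only gene called by edgeR in the fit of all 9 libraries (log2 fold change 1.21, SE 0.14, adjusted p = 0.0234, higher in 3 of 3 clones). FN1 had a log2 fold change of -0.19 (adjusted p = 0.178), KLF2 0.12 (adjusted p = 0.558) and PDCD10 -0.08 (adjusted p = 0.587). The 9 genes with a standard symbol that came next in order of p each had adjusted p = 0.0972. They were the tropomyosin gene TPM2 (0.38), the antiviral gene IFITM3 (0.46), CGREF1 (0.37), the spermidine synthase gene SRM (0.45) and the helicase gene DDX49 (0.43) with higher levels, and the protease receptor gene F2RL1 (-0.40), ANGPT2 (-0.68), the kinase gene PRKACB (-0.29) and the Hippo pathway coactivator gene YAP1 (-0.35) with lower levels, as log2 fold changes.

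The TAGLN call in the fit of all 9 libraries was lost in 6 of the fits that left out 1 library, with log2 fold changes that stayed at 1.17 to 1.23. Its adjusted p was 0.0859, 0.0526 and 0.0562 without wild-type libraries 1, 2 and 3, and 0.1, 0.214 and 0.0626 without knockout clones 21, 22 and 23. At an unadjusted p under 0.05 there were 3078 genes, and DESeq2 called 991 and limma-voom 0.

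With the clone as a block, which sets each treated library against its own clone, edgeR called 899 of 13257 genes, 659 up and 240 down, most of them small. The median size among them was 0.35 on the log2 scale, and 14 genes, 12 up and 2 down, reached 2-fold. TAGLN rose by a log2 fold change of 1.17 (SE 0.12, adjusted p = 8.79e-05). The highest call, at 1.71, was a transcript without a standard gene symbol. Among the highest with such a symbol were TPGS1 (1.47), RTEL1-TNFRSF6B (1.32), a readthrough transcript that overlaps other genes and so is uncertain, CD14, a receptor for bacterial lipopolysaccharide (1.28), OPLAH (1.20), and MRPS24, LSR, ZNHIT2 and SPATA2L. Several of these had low levels. TPGS1 lay at 0.201 to 0.364 CPM in the untreated and 0.454 to 1.01 CPM in the treated clones. CD14 lay at 0.498 to 0.546 and 0.743 to 1.94 CPM, and OPLAH at 0.364 to 0.383 and 0.742 to 1.005 CPM. The lowest were FOSB, an immediate early transcription factor (-1.51), CST1 (-0.78), the protocadherin FAT1 (-0.75), ANGPT2 (-0.70), and SAMD15, AKAP2, SNORA63, FAM196B, GREB1L and ZNF487P. Here too some levels were low, with FOSB at 0.401 to 0.689 CPM untreated and 0.119 to 0.251 CPM treated. SAMD15 lay at 0.498 to 1.02 and 0.178 to 0.537 CPM. Of 36 integrin and focal adhesion genes 4 rose, 5 fell and 27 were not called, or 7 and 5 adjusted over the list alone (camera adjusted p = 0.977). With the block and a GC correction the list was called downward (camera adjusted p = 0.00254, and adjusted p = 0.736 with an estimated correlation). The 5 that fell were integrin subunits, with log2 fold changes of -0.40 for ITGA2 (adjusted p = 0.011), -0.35 for ITGB3 (0.0223), -0.32 for ITGAV (0.0311), -0.29 for ITGB1 (0.0238) and -0.27 for ITGA6 (0.0238), whereas ITGA5 was at -0.04 (0.726). These values are without the GC correction described below, and of the 5 a corrected value is given for ITGA2 alone. The 4 that rose, FLNA, ITGB4, LIMS2 and ZYX, were named after their values were seen. CCM2 rose by 0.30 (0.0347), while FN1 was at -0.23 (adjusted p = 0.0646), both without that correction. All 9 genes named as next to TAGLN in order of p were called in the blocked fit, with adjusted p from 0.0102 to 0.0226.

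These blocked calls followed GC content. Of the higher calls with a known GC content 649 of 651 lay above the median gene, and of the lower calls 215 of 238 below it. After a GC correction in the same fit, added after seeing the data, 174 genes were called, 54 up and 120 down, of which 83 were among the 889 blocked calls with a GC value. TAGLN stayed at 1.01 (SE 0.09, adjusted p = 9.12e-09), and MYL9, a myosin light chain of contractile cells, at 0.60 (adjusted p = 0.001), CLU at 0.38, ANGPT2 at -0.60, FAT1 at -0.70, CST1 at -0.92 and ITGA2 at -0.29, whereas TPM2 was at 0.19 (adjusted p = 0.0725). KLF2 went from 0.09 (adjusted p = 0.528) in the blocked fit to -0.32 (adjusted p = 0.00416) after the correction. MYL9 and CLU were picked after their values were seen. Without clone 23 the uncorrected blocked fit called 0 genes by edgeR, with 2782 at an unadjusted p under 0.05, and without clone 21 it called 526.

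**Figure D4:**
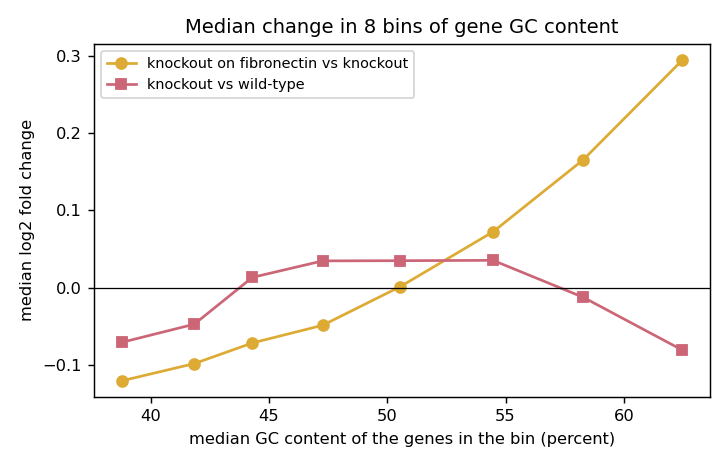
Median log2 difference on fibronectin and median knockout effect (vertical axis) of tested genes in bins of GC content in percent (horizontal axis). On fibronectin the bin medians run from -0.12 to 0.29, and for knockout against wild-type from -0.08 to 0.04.

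Of the gene lists, cytosolic ribosomal proteins alone were called on fibronectin, upward with a median log2 fold change of 0.15 (camera adjusted p = 1.43e-09, and adjusted p = 0.771 with an estimated correlation). None of its 48 members was called by edgeR, and 14 were called when adjusted over the list alone. The next lowest camera adjusted p of the 29 lists was 0.123, for cholesterol synthesis. In the blocked fit 7 rose, or 14 adjusted over the list alone (camera adjusted p = 4.61e-09, and adjusted p = 0.762 with an estimated correlation). In the fit of all 9 libraries, adjusted over the list alone, 8 of the actin contractility genes were higher and 3 lower, 9 and 2 of the cholesterol synthesis genes, 7 and 0 of the p53 targets, 4 and 1 of the interferon response genes, 4 and 0 of the oxidative stress genes, and at most 4 members of any other list, and 0 of the KLF2 and KLF4 axis and the TGF-beta and BMP response. The blocked fit gave larger counts for some other lists, such as the integrin and focal adhesion genes described above. After the GC correction 11 lists were called without the block and 13 of 28 with it, 4 up and 9 down, and none with an estimated correlation (lowest adjusted p = 0.690).

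As a set, the genes changed by the knockout did not shift toward wild-type on fibronectin by the slope over genes. The share of the knockout effect reversed was -2.67% ± 1.98 (SD, n = 3 clones; exact two-sided sign-flip p = 0.25, the smallest that 3 clones can give). As a fraction, data simulated without reversal gave -0.00497, close to clone 23, and the median over genes, fixed in advance as an alternative, was -0.101. By clone the fraction was -0.0441 in clone 21, -0.0308 in clone 22 and -0.00519 in clone 23, over 6856, 6393 and 5966 genes. The genes that moved in the direction of wild-type on fibronectin made up 33.8%, 40.2% and 50.4% of these. The shares were measured without a GC correction. The difference on fibronectin correlated with gene GC content at rho = 0.682, 0.673 and 0.509 in clones 21, 22 and 23. How far that trend shapes the shares was not tested.

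For knockout against wild-type the authors' deposited table gave an adjusted p under 0.05 to 6591 genes, 3291 up and 3300 down, of which 6140 were also called by edgeR here. For knockout on fibronectin against wild-type the authors' deposited table had 7226 such genes, 3556 up and 3670 down, of which 7014 were shared. For fibronectin against none the authors' deposited table had 126, 111 up and 15 down, none at 2-fold or more, of which 1 was shared with the fit of all 9 libraries and 117 with the blocked fit. TAGLN had the largest change in that authors' deposited table, a log2 fold change of 0.85, against 1.21 in the fit of all 9 libraries here. Counts at 2-fold in that table are therefore not comparable with those given here.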

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

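The tests of a GC trend, library depth and smooth muscle cells in this part were chosen after the results were seen, and the counts over other splits of the libraries were fixed before.

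TAGLN stood out because it differed between knockout clones with and without fibronectin, by a log2 fold change of 1.21 in the edgeR fit of all 9 libraries (adjusted p = 0.0234, higher in 3 of 3 clones), while no wild-type library was treated, so that an effect specific to the knockout was not measured. A GC trend as the whole cause is argued against by the blocked fit, where TAGLN went from 1.17 (SE 0.12) to 1.01 (SE 0.09) after a GC correction, while in the fit of all 9 libraries it went from 1.21 (SE 0.14) to 1.03 (SE 0.13) and the call ended at adjusted p = 0.0594, as the genes at an unadjusted p under 0.05 went from 3078 to 1236. Smooth muscle cells or pericytes would bring their other abundant transcripts, but the summed level of ACTA2, MYH11, CNN1, DES and LMOD1 gained 0.225 CPM on fibronectin (SD 0.185 over 3 clones), against 14.8 CPM (SD 6.47) for TAGLN and a bound of 1.48 CPM set at 10% of that, although MYL9 and TPM2, contractile genes that wild-type cells express at 28.6 and 223 CPM, went from 7.27 to 12.9 CPM and from 182 to 237 CPM. This test replaced an earlier form on the summed level itself, which at 5.04 CPM decided nothing because ACTA2 alone lay at 3.80 CPM in wild-type and 4.52 CPM in knockout. An effect of fibronectin on TAGLN may therefore be kept as a hypothesis, with the reservation that the call was lost when any wild-type or untreated knockout library was left out (adjusted p from 0.0526 to 0.214, at log2 fold changes of 1.17 to 1.23).

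The genes called on fibronectin with the clone as a block, 899 in all, may largely reflect a GC trend. Of the 889 with a GC value 83, or 9.34%, were still called after a GC correction in the same fit, and their median size went from 0.35 to 0.13 on the log2 scale. Library depth as the source of that trend is argued against by clone 22, whose treated library was the shallower of its pair (ratio 0.888, against 1.11 and 1.14 in clones 21 and 23), yet the difference on fibronectin correlated with GC content across genes at rho = 0.673 there, against 0.682 and 0.509. The libraries' own correlations with GC content were 0.431, 0.434 and 0.436 on fibronectin and -0.490, -0.182 and 0.0601 in the untreated clones. In wild-type they were -0.106, -0.0858 and -0.371, so libraries of 1 group differed in this trend without any treatment. Whether handling of the treated wells or an effect of fibronectin on GC-rich transcripts lies behind the trend stays open, since no label gives a preparation batch and every treated library shares it.

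Other splits of the 6 libraries of each comparison into 3 and 3 were counted, and 10 splits are too few for a share under 0.05. Every other split mixes libraries of the compared groups, so a large real difference widens the spread within its parts and lowers its calls. A low count of genes in the other splits therefore adds no evidence for the real one. For knockout against wild-type 1 of the 10 splits, the real one, called as many genes (6913, highest other 0), and for knockout on fibronectin against wild-type also 1 (8099, highest other 0). For fibronectin against none 2 of the 10 splits called as many genes (1, highest other 1). For gene lists the numbers were 1 of 10 (10 lists, highest other split 9) and 1 of 10 (10 lists, highest other split 9) against wild-type, and 10 of 10 for fibronectin against none (1 list, highest other split 10). Why a split called several times as many lists as the real one was not tested, and these splits did not keep the pairing of the clones. Of the 4 splits that part the libraries of every clone 1 called as many genes with the clone as a block (899, highest other split 0), and 4 are too few for a share under 0.05 as well. The other splits mix treated and untreated libraries here too.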

How the results depend on the processing

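The settings with a GC correction, the voom form of the blocked fit and the further blocked settings were chosen after the data were seen, and the other alternatives were planned. Both comparisons with wild-type kept their counts of changed genes within 1.5 times under every alternative except a 2-fold minimum, which by construction left 1827 of 6913 and 2010 of 8099. PDCD10 was called lower in the knockout under every alternative, at -0.29 to -0.41 on the log2 scale.

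The count on fibronectin, 1 gene in the fit of all 9 libraries, moved most. It was 991 with DESeq2, 383 with no low-count filter, and 0 with limma-voom, with only the 2 groups compared and with a GC correction, where 3116, 2700 and 1236 genes had an unadjusted p under 0.05. It ran from 0 to 488 with 1 library left out, with 0 without each of the 3 wild-type and the 3 knockout libraries and 488 without clone 22 on fibronectin. With the clone as a replicate block it was 899, and 296 with the block in DESeq2, 1028 in limma-voom and 174 with the block and a GC correction. Taking the 899 as the starting point, the block gave 1661 genes with no low-count filter and 14 at 2-fold, and leaving out the libraries of 1 clone gave 526 without clone 21, 837 without clone 22 and 0 without clone 23 (2782 at an unadjusted p under 0.05). Leaving out a clone leaves fewer samples, the GC correction removes a trend by construction, and for the other settings the cause was not tested.

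The number of called lists was 10 against wild-type in both comparisons, 1 each with an estimated correlation and 21 and 23 with fry, which tests each list without comparing it with other genes and did not call ribosomal proteins in the knockout (adjusted p = 0.0953). With at least 1 CPM in 3 libraries it was 9 and 8, as mesenchymal genes were no longer called in either comparison (adjusted p = 0.0716 and 0.105), nor the oxidative stress response on fibronectin (0.0632). With a GC correction it was 9 and 11, as the interferon response was lost in the knockout (0.053) and the oxidative stress response on fibronectin (0.058), where actin contractility and YAP and TAZ targets were added as lower (0.0327 each). With a minimum of 10 members it was 9 and 9, as histones were not tested, and with 1 library left out it was 10 to 11 and 8 to 10. For fibronectin against none it was 1, against 0 with an estimated correlation, 0 with fry, 11 with a GC correction, 13 with the block and a GC correction, and 1 to 2 with 1 library left out. There it was 2 without each knockout clone and without clone 22 on fibronectin, where cholesterol synthesis (adjusted p = 0.0123 and 0.0252 without knockout clones 21 and 22) or the oxidative stress response (0.034 without knockout clone 23 and 0.00936 without treated clone 22) was added. The block alone changed no list call. YAP and TAZ targets were called lower than wild-type on fibronectin without treated clone 23 (adjusted p = 0.0346). The correlation of the comparisons with wild-type was 0.9733, and 0.9793 over called genes, 0.906 as Spearman's rho and 0.9585 to 0.9737 with 1 library left out. The share reversed was -0.0267, and -0.1008 as a median over genes. The cause of these moves was not tested.

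Of the named genes 1 value turned its direction past the threshold. KLF2 on fibronectin was at 0.12 (adjusted p = 0.558) in the fit of all 9 libraries and at -0.32 (adjusted p = 0.00416) with the block and a GC correction, the lowest of adjusted p-values that ran up to 0.9 over its alternatives. The correction lowers genes of high GC content by construction, and KLF2 has 66.8%. For the other values of named genes the side of the threshold was kept in 2864 cases for knockout against wild-type, gained in 7 and lost in 15, in 2890, 7 and 8 for knockout on fibronectin against wild-type, and in 3238, 161 and 9 on fibronectin. For lists the numbers were 366, 19 and 16, then 365, 16 and 20, then 429, 26 and 2. Leaving out 1 library ended 23 of the called cases, all in TAGLN, TPGS1, RTEL1-TNFRSF6B, LSR, HIST1H4H and EPCAM, and reversed 0. At this depth and number of replicates small changes were often missed, as 56% of 1.5-fold and 90% of 2-fold changes simulated on fibronectin were found without the block. Neither depth nor replicate number was varied.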

Other observations

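The genes in this part were chosen, and its tests set, after the values were seen. The knockout clones nearly lacked the mRNA of a set of genes that every wild-type library expressed. Clonal origin and genotype are not separated here either. Of 10021 genes with at least 5 CPM in each wild-type library, 22 lay below 2% of the wild-type mean in all 3 knockout clones, 4 in 2 clones and 14 in 1. Beyond the genes already described they included BMPR1A, a BMP type I receptor, from 9.36 ± 1.5 to 0.106 ± 0.066 CPM, GREM1, a secreted BMP antagonist, from 14.5 ± 1.85 to 0.0759 ± 0.102 CPM, KIT, the stem cell factor receptor, from 6.70 ± 1.05 to 0.0377 ± 0.0383 CPM, and SDC2, a heparan sulfate proteoglycan, from 7.02 ± 0.463 to 0.108 ± 0.00717 CPM (SD, n = 3 each). Others were ABCA8, AMPH, LYPD1, TMEM47, TUSC3 and ZC4H2, and 21 of the 22 were below that level in every clone on fibronectin too. Of these 22 genes 5 lie on the X chromosome, which was singled out after they were seen, where 339 of 9845 (3.44%) of the genes expressed in wild-type with a known chromosome lie.

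In the other direction 15 of 9890 genes expressed in every knockout clone lay below 2% of the knockout mean in all 3 wild-type libraries, and 15 of 15 were at 5 CPM or more in each clone on fibronectin. Among them were A2M, a plasma protease inhibitor, from 0.0804 ± 0.0512 to 14.1 ± 3.49 CPM, KCNN4, a calcium-activated potassium channel, from 0.221 ± 0.0677 to 15.4 ± 0.0908 CPM, NOSTRIN, which binds endothelial nitric oxide synthase, from 0.159 ± 0.0457 to 11.5 ± 4.99 CPM, and TSPAN7, a tetraspanin, from 0.274 ± 0.019 to 15.3 ± 0.882 CPM (SD, n = 3 each). Of these 15 genes 2 lie on the X chromosome.

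Whole chromosomes shifted between knockout and wild-type, with median log2 fold changes over 10351 genes of -0.17 to -0.07 on 11 chromosomes and of 0.04 to 0.09 on the other 12, and none between. Dealing chromosome labels to genes at random never gave as large a spread (permutation p = 1e-05, the smallest that 100000 draws can give), and a GC correction left the SD of the medians at 103% of its value, which argues against a GC trend. After that correction the sides were the same on all 23 chromosomes, in each of the 6 knockout libraries the groups of chromosomes stayed apart, and no chromosome median of a wild-type library differed from that of the other wild-type libraries by more than 0.0254, against up to 0.118 before it. A difference of 1 chromosome copy in every cell, with expression in proportion, could be the source. The distance of 0.263 between the highest and lowest median lies below the 0.322 that a step from 4 to 5 copies gives. Its bootstrap bound of 0.343 lies above 0.322, so that step cannot be told from the counts. Every step of 1 copy between lower copy numbers gives a distance above that bound, which argues against it for a line with fewer copies. The copy number of the line was not measured here. Higher copy numbers, mixed cells and the clonal origin of the knockout lines were not tested.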
